A study of Mus musculus with 4 samples.

How the data were processed

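Single cells of the prostate were profiled in Pb-PRL mice, a transgenic line in which the probasin promoter drives prolactin in the prostate and which models benign prostate hyperplasia. The treatment was anethole trithione (ATT), a sulfur-containing dithiolethione drug, given at 60 mg/kg/day by gavage for 30 days, and control mice received its vehicle, coconut oil. Per the labels' protocols, tissue was digested with collagenase and trypsin, passed through a 40 µm sieve and sorted for live cells without the erythroid antigen Ter119. Per the labels' protocols, 20000 cells were loaded for each library of the 10x 3' kit version 3.1, which was sequenced with 28 cycles for the cell barcode and 91 for the transcript. Per the submitters' processing notes, the authors used Cell Ranger 5.0.1 with mm10 and Seurat 4.0.1. The values analysed are the UMI counts deposited for each gene and each barcode before any cell was selected, over 32285 genes.

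The labels name 4 mice, 2 per group. Libraries of 3 mice were analysed, vehicle 504, vehicle 756 and ATT 748, and the ATT mouse 506 was not analysed here. Each group held a mouse of 6 months and one of 8 months, which the labels do not tie to a library, so age was not modelled. Total UMIs were 107580847 in vehicle 504, 77833765 in ATT 748 and 20942570 in vehicle 756. Gene positions were taken by Ensembl identifier from the GENCODE vM21 annotation of GRCm38, the assembly that mm10 names, which matched 32158 of the 32285 identifiers and 149 of the 149 genes named by the rule below.

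Barcodes were kept as cells from a floor of 500 UMIs or the inflection point of the ranked UMI totals between ranks 1000 and 50000, whichever was higher, which gave floors of 1768 in vehicle 504, 884 in ATT 748 and 1660 in vehicle 756. Cells needed 300 genes and at most 20% mitochondrial UMIs. Scrublet in scanpy 1.11.5 marked 0, 1 and 9 doublets in vehicle 504, ATT 748 and vehicle 756. The 0.8% per 1000 cells that the loading gives would be 269, 256 and 9. Scrublet thus did not work as a doublet filter in the first 2 of these libraries. The 3 libraries were clustered together on 3000 variable genes, 30 principal components and 15 neighbours with Leiden at resolution 1 (leidenalg 0.10.2, seed 0). The genes of all tested lists, mitochondrial genes and ribosomal genes were kept out of clustering, whereas Prl, Ly6a, Keap1 and Nfe2l2 were not. Clusters with Epcam in at least 60% and Ptprc in under 10% of cells were clustered a second time by themselves. A cluster took the name of a cell class when at least 3 of its markers were detected in 40% of cells and at 0.5 of the highest cluster, its score reached 0.4 and it led the next class by 0.1, or when 10 leading genes decided. The second clustering and these naming thresholds were chosen after the clusters were seen, whereas the 24 marker lists, the 20 tested lists (388 genes), the comparisons, the tests and most alternative settings were fixed before the data were examined. Names stand for likeness in markers (basal-like, luminal progenitor-like, mature luminal-like) and are written below without the ending.

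UMI counts were summed per library and class. Class comparisons were paired within the 3 mice, with library as a block, over 6 sums. ATT was compared with vehicle as 1 library against 2, which leaves 1 residual degree of freedom among libraries, so the lone ATT library is assumed to vary like the vehicle libraries. The difference of the ATT effect between progenitor and mature luminal cells was an interaction term with the mouse as a block. Genes passed filterByExpr, were scaled by TMM and tested by the edgeR quasi-likelihood test (edgeR 4.0.16, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Values are log2 fold changes ± standard error, and levels are CPM, UMI counts scaled by the TMM library size. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and adjusted over 20 lists. With an estimated correlation, camera instead rests on the few residual degrees of freedom among the sums. Lists then seldom pass whatever their correlation, so a failure there does not show that members vary together. Counts of list members that pass after adjustment over the list alone are given beside the counts adjusted over all genes. Shares of cells carry exact Clopper-Pearson 95% intervals, which cover counting error only.

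Genes are named by a rule fixed before the data were examined. In class comparisons, up to 3 members per list with the smallest p were named if they passed and had the same direction in 3 libraries. In ATT comparisons, up to 3 members per list were named, and the 10 higher and 10 lower genes with the largest fold that passed, reached 50 CPM in the higher group and lay outside both vehicle libraries. Where fewer than 5 genes passed, 5 genes per direction were named as values. A fixed set of redox, prolactin and progenitor genes was always named where tested. The rule covers the comparisons of epithelial cells, and genes outside it are marked as chosen after their values were seen.

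The fit was tested on simulated data with 200 genes changed, 100 by 2-fold and 100 by 4-fold. It called 77 and 100 of each 100 in progenitor against mature luminal cells, 89 and 100 in progenitor against basal cells, 5 and 62 for ATT in progenitor cells, 2 and 63 in mature luminal cells, 10 and 94 in basal cells, 9 and 93 in all epithelial cells, and 4 and 26 for the interaction. A 2-fold effect of ATT would thus rarely have been called.

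Alternative settings fixed at that time were DESeq2 size factors in edgeR, the DESeq2 1.42.0 Wald test, no low-count filter, subtraction of free RNA estimated from barcodes under 50 UMIs, at most 10% mitochondrial UMIs, a floor of 1000 UMIs and 500 genes, doublets kept, libraries clustered separately, Leiden resolutions 0.5 and 2, the 20 genes highest in free RNA left out, no replicate block, each library left out, each vehicle library as the lone library, camera with an estimated correlation, and fry. Chosen after the data were seen were the cells with the highest Scrublet scores left out (269 in vehicle 504, 256 in ATT 748, 9 in vehicle 756), the highest UMI floor for every library, a cluster led by Upk3a added to progenitor cells (124 cells), a cluster of low UMI totals left out of mature luminal cells (422 cells), each gene's largest single-cell count lowered to the second largest, DESeq2 and lone vehicle libraries in the other cell classes, and class shares without each vehicle library. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9 were used.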

Results

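The study asks whether oxidative stress and progenitor properties are linked in a prostate enlarged by prolactin, and what ATT changes there. Single-cell UMI counts were analysed for vehicle 504 (5798 cells), vehicle 756 (1040 cells) and ATT 748 (5660 cells), 12498 cells in all. Median UMIs per cell were 12816, 10413 and 8447, and median mitochondrial shares were 3.01%, 2.67% and 3.33%. The ATT group holds 1 library, so no ATT difference below can be separated from a difference between mice.

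Basal cells, marked by Krt5, Krt14 and Trp63, were the largest epithelial class in each of the 3 libraries. They made up 53.1% (95% interval 51.4 to 54.7) of 3536 epithelial cells in ATT 748, 61.4% (59.7 to 63.1) of 3131 in vehicle 504 and 56.9% (53.05 to 60.6) of 686 in vehicle 756. Mature luminal cells, marked by Pbsn and Tgm4 or by Msmb and Spink1, made up 25.5% (24.1 to 27.0), 18.3% (17.0 to 19.7) and 23.5% (20.3 to 26.8). Luminal progenitor cells, led by Psca, Krt4 and Ppp1r1b, were rare at 2.15% (1.70 to 2.68, 76 cells), 2.52% (2.00 to 3.13, 79 cells) and 1.90% (1.01 to 3.22, 13 cells). Epithelial cells left without a name made up 19.3%, 17.8% and 17.8%, and a Upk3a-led cluster of 124 cells among them shared Krt4, Psca and Ly6d with the progenitor cells.

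ATT 748 stood below the mean of the vehicle libraries by −6.06 percentage points for basal cells (SD between vehicle libraries 3.21) and by −0.0598 for progenitor cells (SD 0.444), and above it by 4.64 for mature luminal cells (SD 3.63). With 1 library against 2 no test of these shares was run. Without either vehicle library in turn, the differences ran from −8.33 to −3.80 for basal, from −0.374 to 0.254 for progenitor and from 2.07 to 7.20 for mature luminal cells. The progenitor difference also changed its sign with the clustering, to 2.15 points at Leiden resolution 2 and 3.06 points with libraries clustered separately. The basal cells of vehicle 504 came from other clusters than those of the remaining mice. Clusters led by Dlk2 and Stbd1 or by Clca3a2 and Dapl1 held 87.8% of them, against 5.01% in ATT 748 and 7.44% in vehicle 756, while clusters led by Tead1 and Nrg1, by Krt16 and Col17a1 or by Trp63 and Tenm2 held 2.65%, 82.6% and 87.9%. Mature luminal clusters also differed in size. The cluster led by Sbp, Msmb and Spink5 held 32.3% of mature luminal cells in ATT 748, 45.5% in vehicle 504 and 9.32% in vehicle 756, and that led by Pate14 and Tgm4 held 30.9%, 13.6% and 40.4%.

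**Figure D1:**
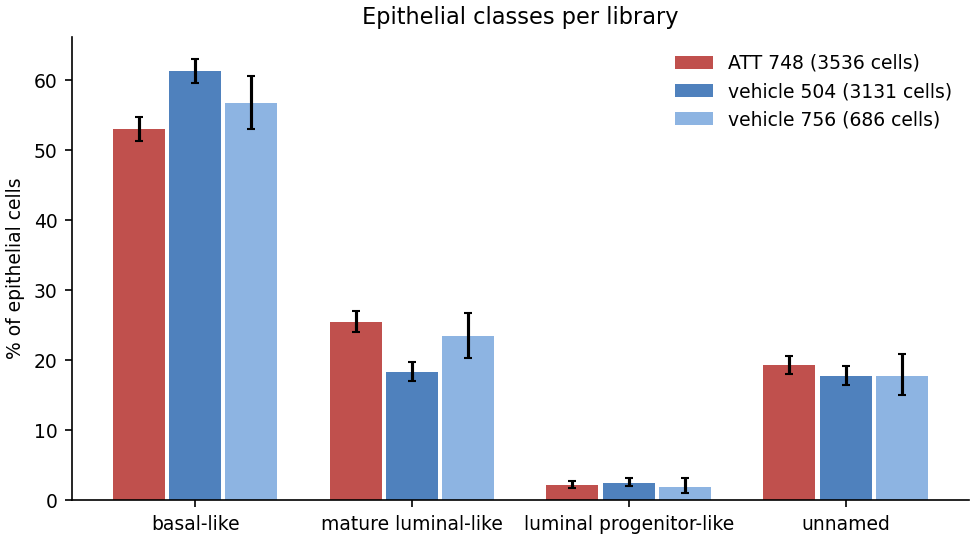
Percent of epithelial cells in each class (bars) with exact 95% intervals in 3 libraries (colours). Basal cells were the largest class in each library, and progenitor cells made up between 1.90% and 2.52%.

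The first comparison asks how the redox genes of progenitor cells differ from those of mature luminal cells of the same mice (n = 3 mice). Gpx3 (ENSMUSG00000018339, mm10 chromosome 11, 54902453 to 54910377), which encodes a secreted peroxidase that uses glutathione, was at 2427 CPM in mature luminal cells and far lower in progenitor cells (log2 −6.15 ± 0.44, adjusted p = 1.93e-06). Prdx6 (chromosome 1, 161240112 to 161251219), a peroxidase that repairs oxidised lipids, was lower at 187 against 1173 CPM (−2.59 ± 0.22, adjusted p = 7.19e-06), a call that ended with libraries clustered separately (−0.97). Sod1, the cytosolic superoxide dismutase, was lower (−1.14 ± 0.17, adjusted p = 0.000447). Gsta4 (ENSMUSG00000032348, chromosome 9, 78182774 to 78209349), which couples glutathione to lipid aldehydes, was higher at 441 against 31.1 CPM (3.85 ± 0.27, adjusted p = 1.55e-06). Prdx5, a mitochondrial and peroxisomal peroxidase, was also higher at 318 against 146 CPM (1.13 ± 0.16, adjusted p = 0.000327).

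Nfe2l2 (ENSMUSG00000015839, chromosome 2, 75675513 to 75704641), which encodes the stress transcription factor NRF2, was at 141 CPM in progenitor and 52.4 CPM in mature luminal cells (adjusted p = 0.000999). Its repressor Keap1 did not pass (−0.51 ± 0.23, adjusted p = 0.121), nor did the NRF2 targets Hmox1 (−0.46 ± 0.21, adjusted p = 0.126), Txnrd1 (0.35 ± 0.16, adjusted p = 0.133), Srxn1 (0.77 ± 0.34, adjusted p = 0.112), Gclc (0.05 ± 0.25, adjusted p = 0.911) and Gclm (0.00 ± 0.17, adjusted p = 0.999). Hmox1 and Gclm were called higher at a mitochondrial limit of 10% (0.49 and 0.40), and Gclc with the Upk3a-led cluster added (1.78). Cyba, a subunit of the superoxide-producing NADPH oxidase, was higher at 134 against 59.7 CPM (1.20 ± 0.23, adjusted p = 0.002), which did not pass without the mouse block (1.25). Cat, the peroxisomal catalase, was higher (1.09 ± 0.27, adjusted p = 0.00978) but did not pass without mouse 748 (1.34) or mouse 504 (1.15). Prdx1 (0.02 ± 0.15, adjusted p = 0.943) and Sod2 (−0.36 ± 0.18, adjusted p = 0.161) did not pass, and Nqo1 fell below the low-count filter.

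Prlr, the prolactin receptor, was at 34.0 CPM in progenitor and 423 CPM in mature luminal cells (−3.60 ± 0.21, adjusted p = 5.66e-07), and Stat5a (−3.31 ± 0.26, adjusted p = 4.02e-06) and Socs2 (−3.11 ± 0.22, adjusted p = 1.84e-06) were lower too. The list of prolactin and STAT5 response genes had 2 of 13 members higher and 6 lower (3 and 7 over the list alone, median −0.60) and did not pass (camera adjusted p = 0.26). Prl itself was at 234 against 11290 CPM (−5.85 ± 0.30, adjusted p = 3.38e-07), but Prl is among the leading genes of a mature luminal cluster and its reads may cover the transgene only in part. Chaperones of the endoplasmic reticulum were lower in progenitor cells, with Sdf2l1 at 11.2 CPM (−4.46 ± 0.29, adjusted p = 1.25e-06), Creld2 at 23.1 against 275 CPM (−3.43 ± 0.23, adjusted p = 1.44e-06) and Hsp90b1 at 350 against 2102 CPM (−2.49 ± 0.20, adjusted p = 4.61e-06). The progenitor marker Ly6a, which encodes Sca-1, was higher at 1539 against 503 CPM (1.62 ± 0.16), but did not pass with libraries clustered separately (1.60). Ccn2, a matrix protein induced by YAP, was higher (4.11 ± 0.29, adjusted p = 1.77e-06) and Timp1, an inhibitor of matrix proteases, was lower (−4.66 ± 0.36, adjusted p = 3.85e-06).

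Among gene groups, members of the AHR and xenobiotic response were higher in progenitor cells, 6 of 6 (6 adjusted over the list alone, median log2 1.63, camera adjusted p = 4.00e-05), led by the receptor Ahr (1.82 ± 0.21, adjusted p = 6.99e-05), Cyp2b10 and Por. Keratins and junctions were higher, with 8 of 15 members higher and 1 lower (11 and 2 over the list alone, median 0.85, camera adjusted p = 0.00108). The unfolded protein response was lower, with 14 of 19 members lower and 0 higher (the same counts over the list alone, median −2.09, camera adjusted p = 3.68e-09). Subunits of respiratory complex I were lower, 13 of 37 with Ndufa1 and Ndufv3 first (15 over the list alone, median −0.42, camera adjusted p = 0.000906). For these 4 lists the camera adjusted p = 0.683 with an estimated correlation. With few residual degrees of freedom that setting cannot tell whether members that vary together carry them.

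The redox lists went both ways within themselves and did not pass. Of 21 NRF2 targets 5 were higher and 6 lower (5 and 7 over the list alone, camera adjusted p = 0.958), and of 26 glutathione enzymes 7 were higher and 5 lower (7 and 7, adjusted p = 0.715). Of 18 genes for superoxide and peroxide removal 2 were higher and 8 lower (2 and 8, adjusted p = 0.388), and of 10 enzymes that produce reactive oxygen species 4 were higher and 2 lower (5 and 3, adjusted p = 0.346). Camera gave NRF2 targets and glutathione enzymes the direction up while their medians were −0.09 and −0.04. Mitochondrially encoded subunits had 4 of 13 members higher (5 over the list alone, adjusted p = 0.0612).

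In all, 3150 of 10684 genes passed, 1343 higher and 1807 lower in progenitor cells. The tested genes include those used to cluster and name the cells, which differ between the classes by construction. DESeq2 called 2203, edgeR without the mouse block 2443, and the vehicle libraries alone 1518. Lowering the largest single-cell counts left 2950 calls, 2782 of them among the 3150. The median of all genes was −0.09, and −0.07 with DESeq2 size factors on the same 10684 genes. It was 0.20 in DESeq2 and −0.46 with no low-count filter, each over 21090 genes and so no measure of a shift of the genes tested here. The folds of the called genes named above are larger in size than each of these medians.

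**Figure D2:**
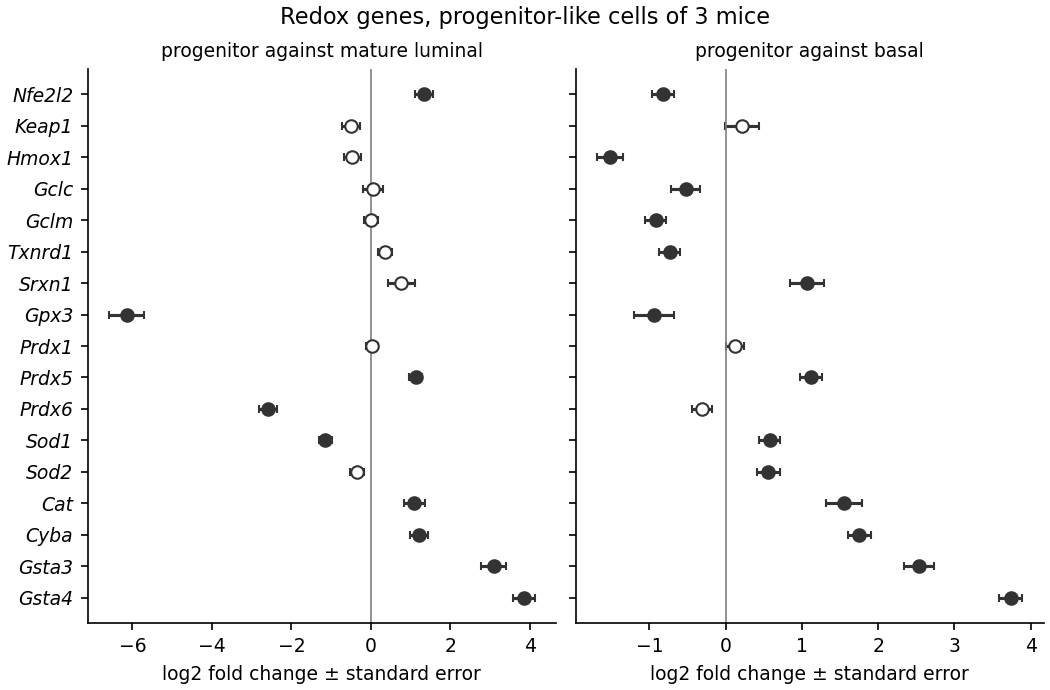
Log2 fold change ± standard error (horizontal axes) of 17 redox genes in progenitor cells against mature luminal cells (left) and basal cells (right), n = 3 mice; filled points passed the edgeR test. Gsta4 was higher and Gpx3 lower in both, and Nfe2l2 lay above mature luminal and below basal cells; Gpx3 and Nfe2l2 turned to the other sign against basal cells in some settings.

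The second comparison sets progenitor cells against basal cells of the same mice (n = 3 mice). Gsta4 was again higher, at 441 against 32.5 CPM (3.74 ± 0.15, adjusted p = 8.78e-13), as were Gsta3 (2.53 ± 0.20, adjusted p = 7.35e-09) and Gsto1 at 1359 against 464 CPM (1.52 ± 0.14, adjusted p = 5.44e-08), which reduces oxidised glutathione conjugates. Cyba (ENSMUSG00000006519, chromosome 8, 122424776 to 122432930) was at 135 CPM in progenitor and 40.2 CPM in basal cells (1.75 ± 0.15, adjusted p = 3.93e-08), and Noxa1, an activator of NADPH oxidase 1, at 10.2 against 0.730 CPM (3.76 ± 0.48, adjusted p = 5.02e-06). Mitochondrial Prdx3 at 41.4 against 15.8 CPM (adjusted p = 7.54e-06), Prdx5 (1.12 ± 0.14, adjusted p = 3.93e-06), Sod1 (0.58 ± 0.14, adjusted p = 0.00266) and Cat at 27.6 against 10.1 CPM (adjusted p = 3.80e-05) were higher. Sod2 was higher (0.56 ± 0.15, adjusted p = 0.0072) but did not pass without mouse 504 (0.39) or without the mouse block (0.58).

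Hmox1 (ENSMUSG00000005413, chromosome 8, 75093621 to 75100589), which degrades heme under stress, was lower at 51.1 CPM (−1.52 ± 0.17, adjusted p = 9.54e-07), and Gclm, the modifier subunit of glutathione synthesis, was lower (−0.92 ± 0.14, adjusted p = 4.31e-05). Txnrd1, a thioredoxin reductase, was lower (−0.73 ± 0.14, adjusted p = 0.000298) except without the mouse block, where it did not pass (−0.70). Srxn1, which reactivates peroxiredoxins, was higher at 102 against 39.6 CPM (1.07 ± 0.22, adjusted p = 0.000861). Nfe2l2 was lower at 141 against 247 CPM (−0.82 ± 0.14, adjusted p = 0.000118) and turned higher when the Upk3a-led cluster was added (0.39), as did Gclc, from −0.53 ± 0.19 (adjusted p = 0.0364) to 1.15. The Gclc call also ended without mouse 748 (−0.66) or mouse 504 (−0.43). Gpx3 was lower (−0.94 ± 0.27, adjusted p = 0.00957) but ended without mouse 748 (−0.58) and turned higher in 5 settings, up to 2.04 with doublets kept, where the progenitor class of vehicle 504 grew from 79 to 121 cells. Keap1 (0.21 ± 0.22, adjusted p = 0.499), Prdx1 (0.12 ± 0.11, adjusted p = 0.439) and Prdx6 (−0.31 ± 0.14, adjusted p = 0.0846) did not pass.

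The luminal keratin Krt8 was higher in progenitor cells at 3186 against 893 CPM (1.83 ± 0.11, adjusted p = 1.57e-10), as was the androgen target Tmprss2 at 246 against 39.8 CPM (2.61 ± 0.14, adjusted p = 5.63e-11). The mucosal chemokine Cxcl17 (ENSMUSG00000060188) was at 298 against 3.23 CPM (6.48 ± 0.24, adjusted p = 2.35e-13). Inflammatory Icam1 was lower at 29.4 against 244 CPM (adjusted p = 2.61e-10), and Lcn2, which binds bacterial siderophores, was at 20.3 against 300.2 CPM (adjusted p = 6.50e-12), a difference that vanished with libraries clustered separately (−0.08). Among growth genes, Stmn1, which loosens microtubules, was lower at 32.0 against 252 CPM (−2.79 ± 0.19, adjusted p = 1.44e-09). Prlr did not pass (0.50 ± 0.20, adjusted p = 0.0581), and Prl (1.12 ± 0.27, adjusted p = 0.00266) ended without mouse 748 (0.38) and turned lower with the highest Scrublet scores left out (−0.64). Ly6a (0.46 ± 0.10, adjusted p = 0.00183) ended without the mouse block (0.44).

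Cell cycle genes were lower, 20 of 24 (21 lower and 1 higher over the list alone, median −2.31, camera adjusted p = 5.72e-07); the basal class holds a cluster of 73 cells led by Ube2c and Top2a and the progenitor class holds no such cluster. Immediate early genes, with Ier3, Junb and Egr1 first, were lower, 18 of 22 against 1 higher (18 and 2 over the list alone, median −0.64, camera adjusted p = 3.23e-05), and these also respond to tissue dissociation. Inflammatory targets of NF-kB were lower, 11 of 18 against 4 higher (the same over the list alone, median −0.99, camera adjusted p = 0.0357). Mitochondrially encoded subunits were higher, 12 of 13 against 1 lower (the same over the list alone, median 0.58, camera adjusted p = 0.000124). The progenitor cluster had a median mitochondrial share of 5.21%, against 2.63% to 3.03% in the 5 largest basal clusters. Also higher were genes for superoxide and peroxide removal, 8 of 18 against 3 lower (8 and 3, median 0.36, camera adjusted p = 0.0491). Androgen targets (7 of 14 against 2, 8 and 3 over the list alone, median 0.50, camera adjusted p = 0.0357), lipid and cholesterol synthesis (10 of 22 against 2, 10 and 3 over the list alone, median 0.56, camera adjusted p = 0.0455) and keratins and junctions (8 of 16 against 2, 8 and 2, median 0.34, camera adjusted p = 0.0357) were higher. With an estimated correlation the adjusted p = 0.721 for lipid synthesis and the adjusted p = 0.532 for the other 7 lists.

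NRF2 targets had 6 of 21 members higher and 8 lower (7 and 8 over the list alone, median 0.03, camera adjusted p = 0.987), and glutathione enzymes 5 of 25 higher and 10 lower (5 and 10, median −0.29, adjusted p = 0.714). Enzymes that produce reactive oxygen species had 4 of 11 higher and 2 lower (4 and 3, median 0.41, adjusted p = 0.166). Complex I subunits had 5 of 37 higher and 3 lower (5 and 3, adjusted p = 0.987). In all, 4077 of 11369 genes passed, 1904 higher and 2173 lower. Here too the tested genes include those used to cluster and name the cells. DESeq2 called 2751, edgeR without the mouse block 2522, and edgeR without mouse 504 2560. The median of all genes was −0.05, and −0.098 with DESeq2 size factors on the same 11369 genes. It was 0.19 in DESeq2 and −0.58 without a low-count filter, each over 22138 genes. Those last medians cover many more genes, so they do not measure a shift of the genes named above.

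**Figure D3:**
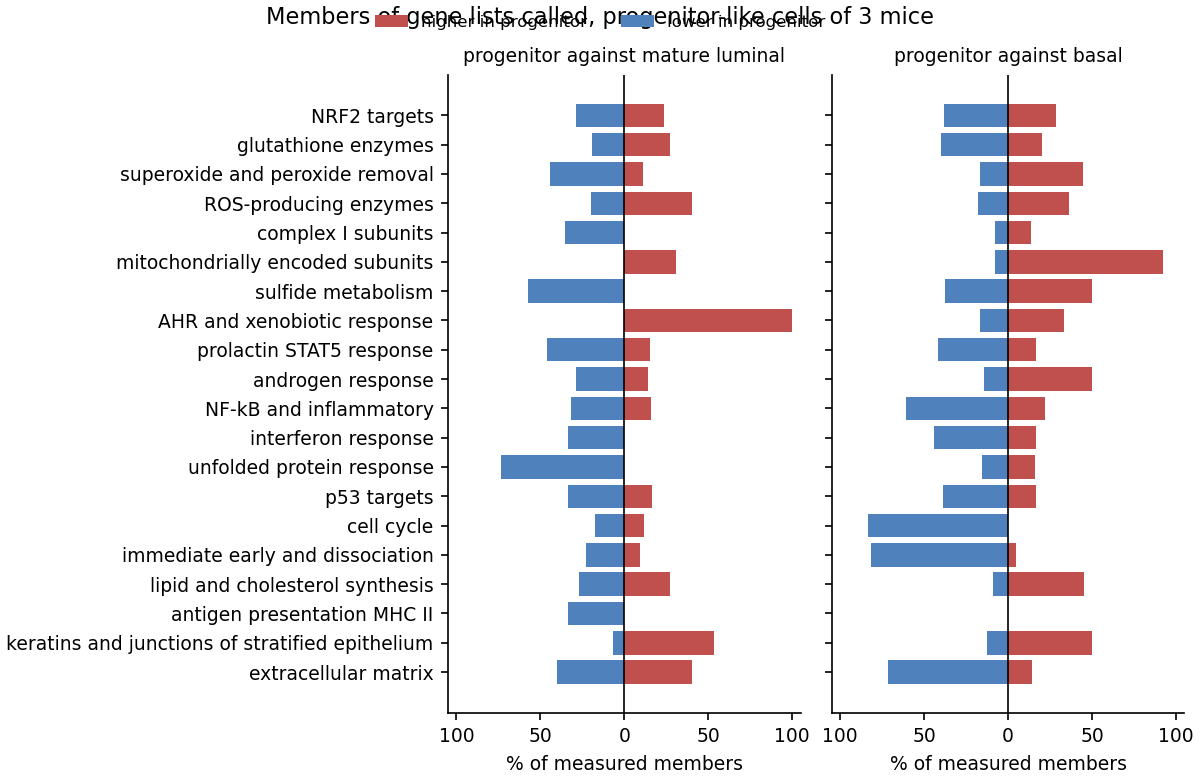
Percent of the measured members of 20 gene lists called higher (red, right of 0) or lower (blue, left of 0) in progenitor cells against mature luminal cells (left) and basal cells (right), n = 3 mice. The unfolded protein response was lower against mature luminal cells, and cell cycle and immediate early genes were lower against basal cells.

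The third comparison asks what ATT changes in progenitor cells, with ATT 748 against both vehicle libraries. No gene of the fixed redox set passed. Nfe2l2 was at 159 CPM with ATT and at 117 and 177 CPM in vehicle 504 and 756 (0.18 ± 0.45) and Hmox1 at 76.0, 50.5 and 36.6 CPM (0.69 ± 0.44), each with an adjusted p = 0.992. Gclc was at 44.3, 21.7 and 36.6 CPM (0.83 ± 0.53), Gpx3 at 21.4, 36.4 and 6.09 CPM (−0.46 ± 0.56) and Cyba at 106, 198 and 128 CPM (−0.69 ± 0.46), each with an adjusted p = 0.992. Gclm (0.14 ± 0.44), Srxn1 (−0.37 ± 0.45), Prdx6 (−0.22 ± 0.45), Sod1 (0.14 ± 0.45), Sod2 (−0.33 ± 0.45) and Prlr (0.49 ± 0.52) had the same adjusted p. Txnrd1 (0.00 ± 0.44, adjusted p = 0.998), Prdx1 (0.02 ± 0.43, adjusted p = 0.998), Cat (0.07 ± 0.53, adjusted p = 0.997), Keap1 (−0.08 ± 0.55, adjusted p = 0.997) and Ly6a (−0.07 ± 0.41, adjusted p = 0.997) did not pass either.

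The keratins Krt6a, Krt16 and Krt17 were among the genes higher in the ATT library. Krt6a was at 454 CPM against 142 and 67.0 CPM in vehicle 504 and 756 (2.00 ± 0.44, adjusted p = 0.00163), Krt16 (ENSMUSG00000053797, chromosome 11, 100246091 to 100248902) at 184 against 28.8 and 79.2 CPM (2.14 ± 0.46, adjusted p = 0.00116) and Sprr2a3, a precursor of the cornified envelope, at 533 against 149 and 18.3 CPM (2.40 ± 0.43, adjusted p = 2.16e-05). Krt17, a basal keratin, was at 229 against 61.4 and 0 CPM (2.34 ± 0.43, adjusted p = 4.06e-05) and turned lower at the floor of 1000 UMIs (−0.09). Ereg, a ligand of the EGF receptor, was at 91.5 against 2.17 and 0 CPM (5.46 ± 0.67, adjusted p = 6.58e-13), and Ltf, which encodes lactoferrin, at 111 against 11.4 and 12.2 CPM (3.25 ± 0.49, adjusted p = 4.26e-08). Of these 6 genes, Krt6a, Krt16, Krt17 and Sprr2a3 did not pass at a mitochondrial limit of 10%, and none of the 6 passed in DESeq2. Over all settings, the call ended or turned in 7 of 13 for Krt17, in 4 of 13 for Krt16 and Sprr2a3 and in 3 of 13 for Krt6a.

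Some of the other called genes rest on single cells. One cell held 97.1% of the UMIs of S100g, 94.1% of Cxcl5, 90.6% of Dmbt1, 88.3% of Cxcl2, 79.5% of Msmb and 76.9% of Prl in the ATT library, and 99.1% of the hemoglobin gene Hbb-bs in the vehicle libraries. Msmb (2.72), Cxcl2 (1.84) and Prl (1.81) turned lower in 4, 4 and 5 settings. Lower genes included Ccl5 at 1.48 against 4.89 and 183 CPM (−5.19 ± 0.88, adjusted p = 2.97e-06), with 76.9% of its UMIs in 1 vehicle cell. Ccl5 was at −1.17 without vehicle 756 and turned higher with libraries clustered separately (1.00). Cebpd was lower at 36.1 against 175 and 36.6 CPM (−1.79 ± 0.47, adjusted p = 0.0257). Cebpd was level with vehicle 756 (−0.02 without vehicle 504). Bhlhe41, a circadian repressor (2.50 ± 0.59, adjusted p = 0.00618), Nrp2 at 63.4 against 14.1 and 0 CPM (2.40 ± 0.54, adjusted p = 0.00287) and mt-Nd6 (1.88 ± 0.47, adjusted p = 0.0136) were higher. Bhlhe41 lost its difference with libraries clustered separately (−0.03), and the call ended or turned in 7 of 13 settings for Bhlhe41, 5 for mt-Nd6 and 4 for Nrp2.

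In all, 57 of 9029 genes passed in edgeR, 42 higher and 15 lower, and over 50% of the UMIs of 23 of them lay in 1 cell. With the largest single-cell counts lowered 23 passed, 17 of them among the 57. DESeq2 called 0 genes, with 47 at an unadjusted p under 0.05 against 464 in edgeR. Vehicle 504 set against the other libraries gave 64 calls and vehicle 756 gave 23.

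**Figure D4:**
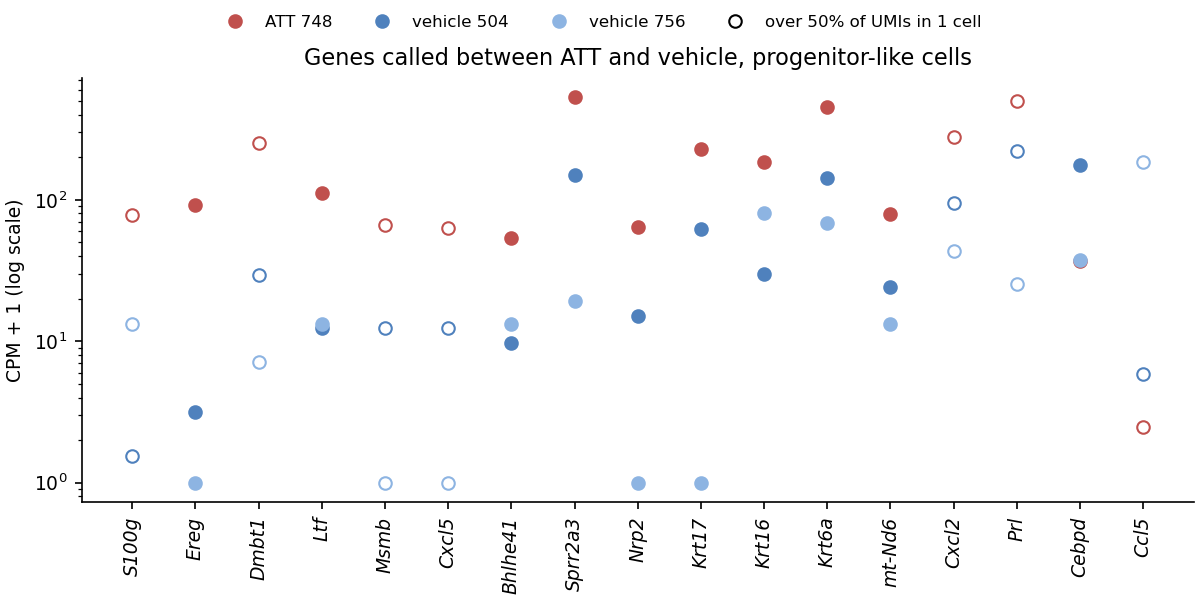
CPM + 1 on a log axis per library (colours) of the genes named by the rule that passed between ATT and vehicle in progenitor cells; open points mark genes with over 50% of their UMIs in 1 cell. Krt6a was at 454 CPM with ATT and at 142 and 67.0 CPM with vehicle, and Prl, Msmb and Dmbt1 rest on 1 cell.

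Keratins and junctions had the lowest p among the 20 fixed lists, with 4 of 16 members higher (5 higher and 1 lower over the list alone, median 0.59, camera adjusted p = 9.79e-05). Basal markers were higher too, 3 of 7 (median 1.51, camera adjusted p = 2.42e-11), and erythroid markers were lower (4 of 5, median −7.80, camera adjusted p = 2.42e-11), with over 99% of the UMIs of Hbb-bs, Hbb-bt, Hba-a1 and Hba-a2 in 1 vehicle cell. With an estimated correlation the adjusted p = 0.703 for keratins and the adjusted p = 0.491 for both marker lists. Complex I subunits were lower with 0 of 37 members called (0 over the list alone, median −0.39, camera adjusted p = 0.00134), which fell to −0.13 without vehicle 504; the adjusted p = 0.742 with an estimated correlation. NF-kB targets (3 of 15 higher, median 0.17, 0.46 without vehicle 504, camera adjusted p = 0.0117), mitochondrially encoded subunits (1 of 13 higher, median 0.26, camera adjusted p = 0.0481) and AHR members (0 of 6, 1 over the list alone, median 0.53, camera adjusted p = 0.0481) also passed, each with an adjusted p = 0.703 with an estimated correlation. Interferon genes (median −0.62, −0.0093 without vehicle 504, camera adjusted p = 0.0481) and immediate early genes (median −0.29, camera adjusted p = 0.0481) were lower, with the same adjusted p = 0.703. The unfolded protein response (median −0.28, camera adjusted p = 0.0486) and MHC II genes (median −1.05, 0.83 without vehicle 504, camera adjusted p = 0.0481) passed, with an adjusted p = 0.742 with an estimated correlation. NRF2 targets had 0 of 20 members called and a median of 0.03 (camera adjusted p = 1).

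In mature luminal cells, Gpx3 was at 1631 CPM with ATT and at 1064 and 4077 CPM in vehicle 504 and 756 (−0.66 ± 0.80, adjusted p = 1), and Prl at 15390, 13080 and 3296 CPM (0.91 ± 0.89, adjusted p = 1). Nfe2l2 (0.12 ± 0.42), Hmox1 (0.28 ± 0.47), Gclc (0.43 ± 0.39), Nqo1 (−0.26 ± 0.85) and Cyba (−0.61 ± 0.62) did not pass, each with an adjusted p = 1. Scgb2b27 at 120 against 0.119 and 0 CPM (adjusted p = 1.26e-05) passed, as did Chga, a neuroendocrine granule gene, at 13.7 against 0 and 0 CPM (adjusted p = 0.0166). In both genes 1 cell held nearly all of the UMIs, 99.6% and 98.4%. Ren1, the renin gene, was at 68.8 against 14.3 and 14.9 CPM (2.24 ± 0.36, adjusted p = 0.163), and the seminal vesicle gene Svs6 at 8.34 against 68.0 and 264 CPM (−4.30 ± 0.79, adjusted p = 0.412); both passed with DESeq2 size factors in edgeR. Of 14255 genes 2 passed, 3 in DESeq2, and 28 and 31 with vehicle 504 and vehicle 756 as the lone library.

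Complex I (median −0.26, −0.15 without vehicle 504, camera adjusted p = 0.0011), androgen targets (median 0.14, 0.23 without vehicle 756, camera adjusted p = 0.00317) and MHC II genes (median −0.55, −0.89 without vehicle 756, camera adjusted p = 0.00317) passed in mature luminal cells with 0 members called, and the adjusted p = 0.918 with an estimated correlation. Mature luminal markers were higher (median 0.29, camera adjusted p = 2.02e-05) and those of seminal vesicle lower (median −0.83, camera adjusted p = 0.00133), with an adjusted p = 0.807 with an estimated correlation.

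In basal cells, interferon genes were higher in the ATT library. Gbp2 (ENSMUSG00000028270, chromosome 3, 142620602 to 142638008), a GTPase induced by interferon gamma, was at 47.0 CPM against 8.43 and 9.80 CPM in vehicle 504 and 756 (2.38 ± 0.39, adjusted p = 2.21e-06), and the antiviral gene Rsad2 at 46.2 against 17.1 and 3.27 CPM (2.09 ± 0.38, adjusted p = 7.45e-05). The interferon list had 4 of 18 members higher (4 over the list alone, median 0.27, 0.45 and 0.13 without vehicle 504 and without vehicle 756, camera adjusted p = 7.12e-08), with an adjusted p = 0.89 with an estimated correlation. A basal cluster of 46 cells led by Gbp2, Cxcl10 and Rsad2 held 38 cells of ATT 748, 6 of vehicle 504 and 2 of vehicle 756. Also higher were Tgm4 at 134 against 18.6 and 56.5 CPM (1.86 ± 0.39, adjusted p = 0.00166) and Pate14 at 58.7 against 5.23 and 15.5 CPM (2.59 ± 0.39, adjusted p = 1.40e-07), and both ended when free RNA was subtracted (1.44 and 0.55). Free RNA was estimated at 5.92% of basal UMIs in ATT 748, 3.69% in vehicle 504 and 0.394% in vehicle 756.

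Seminal vesicle markers (2 of 6 higher, median 1.88, camera adjusted p = 2.00e-10) and mature luminal markers (1 of 8 higher, median 0.62, camera adjusted p = 2.00e-10) were higher with them in basal cells, with an adjusted p = 0.809 with an estimated correlation. Complex I was lower (median −0.45, −0.13 and −0.73 without vehicle 504 and without vehicle 756, camera adjusted p = 5.20e-08), as were immediate early genes (median −0.26, camera adjusted p = 0.0148). Androgen targets (1 of 14 higher, 4 over the list alone, median 0.22, camera adjusted p = 3.04e-07), cell cycle (median 0.29, 0.68 and 0.12 without vehicle 504 and without vehicle 756, camera adjusted p = 3.58e-05) and matrix genes (median 0.69, camera adjusted p = 0.00042) were higher. Each of these 5 lists had an adjusted p = 0.89 with an estimated correlation, and matrix genes turned lower with free RNA subtracted (camera adjusted p = 0.388). Nfe2l2 (−0.06 ± 0.43), Hmox1 (0.17 ± 0.42), Gclc (0.46 ± 0.39), Nqo1 (0.56 ± 0.72) and Gpx3 (0.31 ± 0.39) did not pass, each with an adjusted p = 1. NRF2 targets had a median of 0.18 (camera adjusted p = 0.601). In all, 37 of 15036 genes passed, 27 higher and 10 lower, against 2 in DESeq2. Vehicle 504 as the lone library gave 3681 calls and vehicle 756 gave 38.

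Over all epithelial cells except the seminal vesicle cluster (51, 5 and 10 cells in ATT 748, vehicle 504 and vehicle 756), Sbp, a secreted spermine-binding protein, was at 1597 CPM with ATT and at 339 and 48.0 CPM in vehicle 504 and 756 (3.04 ± 0.57, adjusted p = 0.00444), and Svs6 at 3.06 against 47.4 and 72.3 CPM (−4.29 ± 0.47, adjusted p = 2.90e-08). Both calls ended with the largest single-cell counts lowered. Saa3, an acute phase gene, was lower (−3.54 ± 0.81, adjusted p = 0.0388), but turned higher without vehicle 504 (1.53). Nfe2l2 (−0.08 ± 0.40), Hmox1 (0.12 ± 0.39), Gclc (0.63 ± 0.35), Nqo1 (0.97 ± 0.49) and Gpx3 (−0.29 ± 0.56) did not pass, each with an adjusted p = 1.00. In all, 29 of 17049 genes passed, 18 higher and 11 lower, 8 in DESeq2 and 1 with the largest single-cell counts lowered. Vehicle 504 and vehicle 756 as the lone library gave 2637 and 82 calls.

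Across all epithelial cells complex I was lower (median −0.37, −0.0947 and −0.59 without vehicle 504 and without vehicle 756, camera adjusted p = 7.06e-07), as were MHC II genes (0 members called, 5 lower over the list alone, median −1.18, −0.60 without vehicle 504, camera adjusted p = 8.19e-10) and immediate early genes (median −0.23, camera adjusted p = 0.00643). Androgen targets (1 higher, median 0.17, 0.00868 and 0.27 without vehicle 504 and without vehicle 756, camera adjusted p = 2.84e-06) and interferon genes (1 higher, median 0.06, −0.0862 without vehicle 756, camera adjusted p = 0.0257) passed upwards, and the adjusted p = 0.788 with an estimated correlation for each of the 5. Mature luminal markers were higher (1 of 8, median 0.51, camera adjusted p = 3.83e-11) and endothelial markers lower (median −1.47, camera adjusted p = 1.32e-05), with an adjusted p = 0.76 with an estimated correlation. NRF2 targets had a median of 0.16 and did not pass. The sums of all epithelial cells include an unnamed cluster with Ptprc, a leukocyte gene, in 65.5% of its cells. It held 25 cells in ATT 748, 56 in vehicle 504 and 6 in vehicle 756. Whether this cluster carries the lower MHC II genes was not tested.

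The last comparison tests whether the ATT effect differed between progenitor and mature luminal cells. In progenitor cells Ltf was at 103 CPM with ATT against 10.7 and 10.8 CPM in vehicle 504 and 756. In mature luminal cells it was at 105 CPM against 198 and 31.6 CPM (difference 3.90 ± 0.60, adjusted p = 1.08e-07). Ivl, a precursor of the cornified envelope, differed by 3.83 ± 0.59 (adjusted p = 1.34e-07). In all, 46 of 11645 genes passed, 35 with a positive difference (the effect in progenitor cells minus that in mature luminal cells), 22 with the largest single-cell counts lowered, and 0 in DESeq2, with 65 at an unadjusted p under 0.05 against 335 in edgeR. Vehicle 504 as the lone library gave 98 and vehicle 756 gave 6. NF-kB targets (3 higher, median 0.49, 0.19 without vehicle 504, camera adjusted p = 0.0073) and the unfolded protein response (median −0.42, −0.00866 and −0.70 without vehicle 504 and without vehicle 756, camera adjusted p = 0.0073) passed as lists, with an adjusted p = 0.839 with an estimated correlation. Basal markers had 4 of 8 members higher (median 2.34, camera adjusted p = 2.23e-12), with an adjusted p = 0.605 with an estimated correlation.

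**Figure D5:**
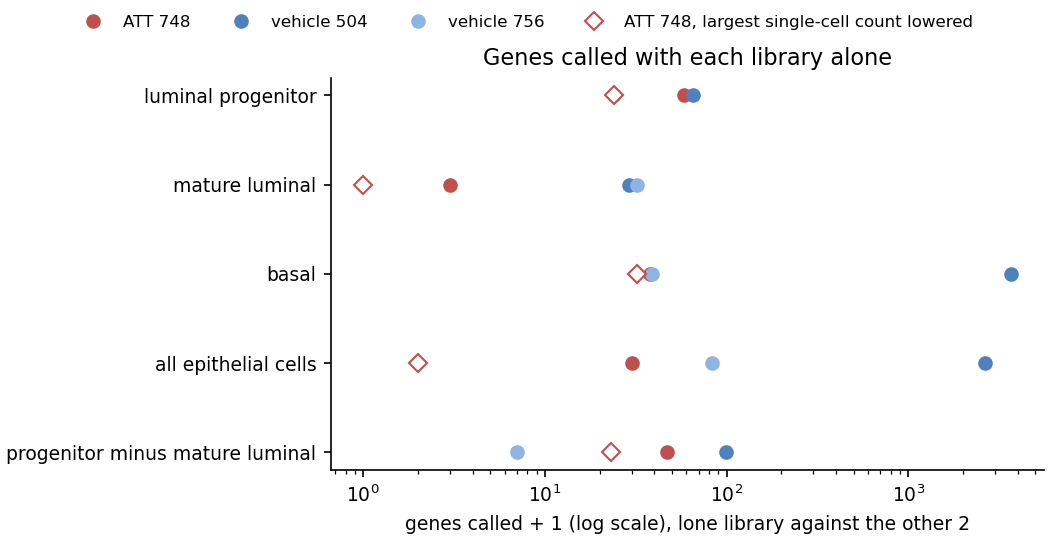
Genes called + 1 on a log axis for each comparison (vertical axis) with ATT 748, vehicle 504 or vehicle 756 as the lone library (points), and for ATT 748 with the largest single-cell counts lowered (diamonds). In basal cells vehicle 504 gave 3681 calls against 37 for ATT 748.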

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

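The tests of single-cell counts and of differences between mice as sources of the progenitor calls were chosen only after those calls were seen.

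The ATT effect differed between luminal progenitor and mature luminal cells in 46 of 11645 genes, by an interaction test of the difference itself in edgeR, and the 7 genes below stood out by that test. The 7 genes are those named by the fixed rule that passed. With vehicle 504 as the lone library the same test called more genes than with ATT 748, and DESeq2 called none. These calls therefore cannot be told from a difference between mice. Values per gene are CPM in ATT 748, vehicle 504 and vehicle 756. Ltf, which encodes lactoferrin, differed by 3.90 (adjusted p = 1.08e-07), with 103, 10.7 and 10.8 in progenitor cells and 105, 198 and 31.6 in mature luminal cells. Ivl, a precursor of the cornified envelope, differed by 3.83 (adjusted p = 1.34e-07), with 84.8, 20.4 and 27.1 against 6.65, 25.9 and 19.8. Krt13, a mucosal keratin, differed by 3.09 (adjusted p = 0.0157), with 53.8, 15.3 and 10.8 against 2.26, 4.36 and 9.02. Sprr2a3 differed by 2.40 (adjusted p = 0.00078), with 498, 140 and 16.2 against 127, 70.0 and 241. These 4 differences kept their sign but not their size: Ltf was 1.49 without vehicle 504, Ivl 0.20 with libraries clustered separately, Krt13 1.68 at a mitochondrial limit of 10% and Sprr2a3 0.961 without vehicle 756.

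Msmb, a secreted luminal protein, differed by 3.14 (adjusted p = 3.66e-05), with 60.7, 10.7 and 0 CPM in progenitor cells and 3861, 5982 and 130 CPM in mature luminal cells of the same libraries, where the Msmb-led cluster made up 32.3%, 45.5% and 9.32% of mature luminal cells. The chemokine Cxcl2 differed by 2.74 (adjusted p = 2.68e-05), with 259, 88.7 and 37.9 against 107.5, 219 and 138 CPM. Its relative Cxcl5 differed by 2.50 (adjusted p = 0.0314), with 57.9, 10.7 and 0 against 28.2, 28.0 and 7.63 CPM. These 3 differences turned to the other sign in some settings: Msmb in 4 (down to −4.31), Cxcl2 in 3 (down to −0.998) and Cxcl5 in 2 (down to −1.05). None of the 7 genes passed in DESeq2, and Ltf, Ivl and Sprr2a3 still passed with the largest single-cell counts lowered.

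In progenitor cells 57 genes were called between ATT 748 and the vehicle libraries, with 4 lower hemoglobin genes first by p and Krt17, Krt16 and Krt6a among the higher ones. Counts of single cells could account for many of the calls, since 17 of 57 were called again once each gene's largest single-cell count was lowered. Krt6a, Krt16, Krt17, Ereg, Ltf and Sprr2a3 stayed past the threshold in that test, which lowers 1 cell only, so a handful of cells stays open for them: Krt16 was seen in 12 and Ltf in 17 of 76 cells. Differences between mice that treatment does not explain could account for as many calls, since vehicle 504 as the lone library gave 64. An effect of ATT on these keratins stays open, and so does a difference between mice, because ATT 748 is the only treated library here. Krt17 is a basal marker, Krt16 and Krt6a are among the leading genes of a basal cluster, and basal markers as a list were higher in these cells too. Whether basal RNA among the progenitor cells, from joined droplets or from cells named wrongly, carries these calls was not tested.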

How the results depend on the processing

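The settings with the Upk3a-led cluster added, the common UMI floor, the highest Scrublet scores left out, the low-UMI luminal cluster left out and the largest single-cell counts lowered were chosen only after the data were seen, as were all settings for the other cell classes.

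Over genes and settings with a test, 3946 values kept their direction and their side of the threshold, 275 fell short of it, 25 newly passed, 140 changed sign without a call and 51 turned direction. In the settings of 1 library against 1, which have no test, 179 stayed within 1 standard error, 94 moved further and 1 turned direction. With the leave-one-out settings set aside, 1079 of 1161 stayed the same against mature luminal cells and 981 of 1078 against basal cells. Both counts still include the setting of the vehicle libraries alone. Between ATT and vehicle in progenitor cells 313 of 433 stayed the same. The cause was not tested for any change below. Settings that change the cells also redraw the progenitor class, from 76, 79 and 13 cells in ATT 748, vehicle 504 and vehicle 756 to 127, 211 and 33 at a mitochondrial limit of 10%, and to 80, 121 and 15 with doublets kept, where only 10 cells were added in all. All ATT results in progenitor cells rest on these small sums.

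The classes are paired by mouse, and without that replicate block progenitor against basal cells gave 2522 calls instead of 4077, and against mature luminal cells 2443 instead of 3150. Both vehicle libraries alone gave 1518 calls against mature luminal cells. Leaving out 1 mouse gave 1518 to 3075 calls against mature luminal and 2560 to 4237 against basal cells. Leaving out 1 vehicle library, which leaves 1 against 1 and no residual degrees of freedom, moved the MHC II median in progenitor cells (−1.05) to between −1.12 and 0.83, Saa3 in all epithelial cells (−3.54) to between −4.50 and 1.53, and the interferon median there (0.0557) to between −0.0862 and 0.0549.

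At a mitochondrial limit of 10%, genes against mature luminal cells turned higher: Xdh 0.22, Rsad2 1.22, Bst2 0.0683, Ifit1 1.24, Hmox1 0.49 and Gclm 0.40. Against basal cells Rsad2 (3.78), Fn1 (0.81) and Gpx3 (1.80) turned. Between ATT and vehicle in progenitor cells Msmb (−4.34) and Prl (−0.28) turned, and Msmb in the interaction (−4.31). Mature luminal cells gave 1 call (2 in the main analysis), the interaction 27 (46), and the progenitor share difference was −2.18 (−0.0598). The split in progenitor cells was 28 higher and 40 lower (main 42 and 15), and in the interaction 16 and 11 (main 35 and 11).

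At the floor of 1000 UMIs and 500 genes, Mki67 against mature luminal cells (0.14) and Ahr (−0.0407), Sparc (0.0684) and Gpx3 (1.76) against basal cells turned. With ATT in progenitor cells Msmb (−4.02), Krt17 (−0.0882) and Prl (−1.02) turned, as did Msmb in the interaction (−3.85). Progenitor cells gave 96 calls (57), 27 higher and 69 lower, mature luminal cells 1, and the interaction 25 higher and 41 lower. Share differences were −0.962 for basal (−6.06) and −0.854 for progenitor cells.

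With the common UMI floor, Ahr (−0.0558) and Gpx3 (1.96) against basal cells turned, with ATT in progenitor cells Msmb (−4.19), Cxcl2 (−0.61) and Prl (−1.09), and in the interaction Msmb (−4.07) and Cxcl5 (−0.96). Progenitor cells gave 112 calls, 32 higher and 80 lower, the interaction 20 higher and 46 lower, and the progenitor share difference was −0.760.

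With doublets kept, Gpx3 against basal cells (2.04) turned, with ATT in progenitor cells Msmb (−1.84), Cxcl5 (−0.84), Cxcl2 (−1.997) and Prl (−1.28), and in the interaction Msmb (−1.82), Cxcl2 (−0.998) and Cxcl5 (−1.05). Progenitor cells gave 89 calls (25 higher, 64 lower), mature luminal 4 (3 and 1), all epithelial 19 (14 and 5, main 18 and 11 of 29), and the interaction 18 higher and 32 lower. The progenitor share difference was −0.760. With the highest Scrublet scores left out, Prl turned against basal cells (−0.64) and with ATT in progenitor cells (−0.24), mature luminal cells gave 1 call, and basal cells 12 higher and 21 lower (main 27 and 10).

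With libraries clustered separately, Ube2c against basal cells (0.45), Cxcl2 (−0.95), Bhlhe41 (−0.0268) and Ccl5 (1.00) with ATT in progenitor cells, and Cxcl2 in the interaction (−0.0715) turned. Calls were 1926 against mature luminal cells (3150), and with ATT 8 in mature luminal (3 higher, 5 lower), 154 in basal (141 and 13, main total 37), 5 in all epithelial cells and 8 in the interaction (8 and 0). Share differences were −2.13 for basal, 3.06 for progenitor and 11.3 for mature luminal cells (4.64). Leiden resolution 0.5 gave −2.58 for basal cells and no progenitor class, so no progenitor value, and resolution 2 gave 2.15 for progenitor cells.

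With the Upk3a-led cluster added, Akr1b8 against mature luminal cells (3.54) and Ethe1 (0.0945), Nfe2l2 (0.39) and Gclc (1.15) against basal cells turned, and the interaction gave 25 higher and 13 lower. With free RNA subtracted, Gpx3 against basal cells (0.97) turned, as did Prl (−12.71) and Gpx3 (−12.24) with ATT in basal cells. There the MHC II (adjusted p = 0.0124) and matrix (adjusted p = 0.388) lists turned in camera, while progenitor cells kept 3 of 9 lists and mature luminal cells gave 1 call. The split was 10 higher and 17 lower in basal and 21 and 21 in all epithelial cells, where leaving out the 20 top ambient genes gave 15 and 5.

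With the largest single-cell counts lowered, Cxcl2 turned with ATT in progenitor cells (−0.79) and in the interaction (−0.0912). Calls were 23 in progenitor (20 higher, 3 lower), 0 in mature luminal, 1 in all epithelial cells and 22 in the interaction (19 and 3), and 7 in endothelial (23), 10 in macrophage (167) and 2 in T cells (17). The 0 in mature luminal cells is from edgeR, with 69 genes at an unadjusted p under 0.05, and DESeq2 gave 3 on unlowered counts.

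DESeq2 gave 0 calls in progenitor cells (47 at an unadjusted p under 0.05, edgeR 57) and 0 in the interaction (65, edgeR 46), 2 in basal (2 higher, 0 lower) and 8 in all epithelial cells (4 and 4). In other classes it gave 1 in endothelial, 2 in fibroblast, 24 in macrophage and 2 in T cells. DESeq2 size factors in edgeR gave 5 calls in mature luminal (4 and 1) and 8 in all epithelial cells (6 and 2). Without a low-count filter mature luminal cells gave 14 (7 and 7), and without the low-UMI luminal cluster 1. Camera with an estimated correlation and fry each passed 0 lists in all 7 comparisons, where camera with its preset correlation passed 4, 8, 9, 3, 6, 5 and 2.

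Vehicle 504 as the lone library gave 28 calls in mature luminal, 3681 in basal (2037 higher, 1644 lower), 2637 in all epithelial cells and 98 in the interaction (44 and 54), with 26 higher and 38 lower in progenitor cells. In other classes it gave 512 in endothelial, 0 in fibroblast (edgeR, 2167 at an unadjusted p under 0.05, DESeq2 178, 14 with ATT 748) and 162 in T cells. Vehicle 756 as the lone library gave 23 in progenitor (2 and 21), 31 in mature luminal, 82 in all epithelial cells (23 and 59) and 6 in the interaction, 12 higher and 26 lower in basal cells, and 30 in fibroblast, 29 in macrophage, 81 in NK (0 with ATT 748 in edgeR, 65 at an unadjusted p under 0.05, DESeq2 0) and 71 in T cells.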

Other observations

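The tests on luminal transcripts in macrophages were chosen only after those transcripts were seen. For the tests on the basal cells of vehicle 504 and on other splits of the samples, the possible outcomes were written before the results of these tests. That the basal cells of vehicle 504 stand apart was itself seen in these data. Apart from members of fixed lists, the genes named in this part were chosen after their values were seen, and no test backs them as a group.

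Macrophages had 167 of 9695 genes called between ATT 748 and the vehicle libraries, with the luminal and seminal vesicle transcripts below among those with the largest folds. Fcna, a secreted lectin, was at 549 CPM with ATT and at 36.8 and 74.4 CPM in vehicle 504 and 756 (log2 3.36 ± 0.42, adjusted p = 2.17e-09), and Lyve1, a hyaluronan receptor, at 291 against 15.3 and 95.4 CPM (2.52 ± 0.46, adjusted p = 8.65e-05). A macrophage cluster of 158 cells led by Retnla, Ccl8 and Fcna held 136 cells of ATT 748, 15 of vehicle 504 and 7 of vehicle 756. Keratin and mast cell genes were among the lower ones, with Krt14 at 27.1 against 457 and 110 CPM (−3.41 ± 0.54, adjusted p = 3.87e-06) and all UMIs of Cma1, Tpsb2 and Cpa3 in 1 vehicle cell each. Of the 167 genes 101 were higher and 66 lower, against 24 calls in DESeq2 and 10 with the largest single-cell counts lowered. Vehicle 504 as the lone library gave nearly as many, 160 in edgeR and 23 in DESeq2.

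Endothelial cells of ATT 748 had more of the chemokine gene Ccl4, at 88.5 against 6.29 and 2.71 CPM (3.93 ± 0.56, adjusted p = 1.98e-08, 55.9% of the UMIs in 1 cell), and of Ccl5, at 106 against 33.9 and 0 CPM (2.15 ± 0.50, adjusted p = 0.0111). The leukocyte genes Gzmb (5 cells, 69.9% in 1 of them) and Ccl3 (7 cells, 77.0% in 1) were higher with them. Fibroblasts had Cfd, which encodes complement factor D, at 56.6 against 0 and 0 CPM (adjusted p = 2.19e-18), from 3 of 596 cells with 66.7% of its UMIs in 1, and the smooth muscle gene Myh11 was lower at 5.07 against 37.7 and 45.3 CPM (−3.00 ± 0.66, adjusted p = 0.00862). In T cells Havcr2, a checkpoint receptor, was higher at 104 against 10.2 and 31.1 CPM (2.73 ± 0.62, adjusted p = 0.00777). Endothelial cells gave 23 calls, 7 higher and 16 lower, with hemoglobin genes and the luminal genes Pate14, Tgm4, Prl and Spink1 among the lower ones. Fibroblasts gave 14 (8 and 6) and T cells 17 (9 and 8, with over 50% of the UMIs of 12 of them in 1 cell). DESeq2 called 1, 2 and 2. NK cells gave 0 in edgeR and 0 in DESeq2, with 65 genes at an unadjusted p under 0.05 in edgeR. Endothelial cells made up 5.90% of all cells in ATT 748, 16.4% in vehicle 504 and 3.37% in vehicle 756. The seminal vesicle cluster made up 0.901%, 0.0862% and 0.962% (51, 5 and 10 cells), so by share ATT 748 was close to vehicle 756.

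Basal cells of vehicle 504 stood apart from those of the other libraries in 3681 genes, with Gm42418 at 8989 against 1747 and 1122 CPM, Tgm4 at 18.6 against 134 and 56.5 CPM in ATT 748 and vehicle 756, and 29 of 37 complex I subunits higher (median 0.65, camera adjusted p = 6.66e-16). Gm42418 had the highest mean share of the free RNA (1.80%) and Tgm4 is a mature luminal marker, so the counts of these genes need not stem from basal cells. Of 18 genes for superoxide and peroxide removal 10 were higher and 0 lower (median 0.43, camera adjusted p = 0.000751), and the adjusted p = 0.802 for both lists with an estimated correlation. Depth of the library does not account for this, since 2364 of the 3681 calls returned after the sums were thinned to the lowest total. Free RNA does not account for most of these calls either, with 2590 of the 3681 returning after the ambient profile was subtracted. A few genes did not take most of the counts, since the 20 highest held 14.6% of them on average. Leaving these 20 out, with 3651 of 3667 calls returning, could therefore change little and tests nothing further. Differences in the mouse, its age, the dissection or the handling of the sample stay open and were not tested.

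Luminal and seminal vesicle transcripts were higher in macrophages of ATT 748, with Svs5 (8.45), Prl (5.59), Pate4 (7.98), Svs6 (7.75), Spink1 (4.43), Svs4 (4.04) and Svs2 (9.04). Free RNA does not account for all of these counts, since relative to the ambient profile they differ 31.37-fold. That spread includes the cell with the most UMIs of each gene, so it does not test the counts of the remaining cells. Without that cell, counts ran from 0.00698 (Spink1) to 0.0159 (Svs4) times the ambient profile, apart from Prl at 0.0905. For those remaining counts free RNA stays open. Single cells that hold the RNA of several cell types could, since in 7 of these 7 genes, the called members of the fixed marker lists and Prl, over 50% of the count lay in 1 cell. Of other luminal genes called in these cells, named after their values were seen, 1 cell held 86.8% of Dmbt1, 75.6% of Agr2, 74.2% of Spink5 and 58.95% of Pigr, but only 48.9% of 9530002B09Rik, 47.7% of Slc12a2 and 34.6% of 5430419D17Rik. Uptake of secretory cells by a macrophage stays open beside joined droplets and was not tested.

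The 6 sums of progenitor and mature luminal cells, or of progenitor and basal cells, allow only 10 splits into 3 and 3, too few for a share under 0.05. The real split alone gave 2443 and 2522 calls without the mouse block, 1 of 10 in each case, and the highest of the other splits gave 0. The classes were cut by clustering on the expression of these same cells. The real split was thus bound to give the most calls, and no conclusion is drawn from it.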
